A study of Mus musculus with 10 samples.

How the data were processed

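Gene expression was measured in J1 cells, a mouse embryonic stem cell line, at 96 hours (day 4) after transfection with small interfering RNAs (siRNAs). The siRNAs were a non-targeting control (NT) or targeted Ino80, Ino80b, Ino80c or Ino80e. Each of the 5 groups held 2 samples that the series' design text calls biological replicates, and each sample was hybridised to 1 array, for 10 arrays in all. Groups and replicate numbers were taken from the sample labels. All comparisons, gene lists, tests, thresholds and alternatives, except where said otherwise, were chosen before the data were examined.

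The arrays were Agilent 4x44K expression arrays, read in 1 colour (green channel), whereas the labels name the dye Cy5. Per the file headers, spots were quantified with Feature Extraction 9.5.3.1. Each deposited scanner file gives the intensity of 45018 spots as a processed signal, which is background-subtracted and detrended within the array and not scaled between arrays, per the file headers. The authors' deposited value table holds log2 values. Set against the scanner files, each of its columns equalled the log2 mean signal of the same array plus 1 constant per array, without background subtraction, and the column medians lay between 6.76 and 6.87. The origin of those constants is not given in the sources used here, so the scaling between arrays of that table stays unknown. Its scale and direction were settled by this match, and genes were not centred.

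Control spots were left out, which left 43379 spots of 41174 probes. Spots with an outlier flag were left out too, and 31 probes without an unflagged spot on some array were dropped, leaving 41143. Spots of the same probe were averaged. The processed signal was log2 transformed and the 75th percentile of each array was subtracted from it, so that every level below is on the log2 scale relative to that percentile. Between 66.4% and 79.0% of probes were well above background on an array, the 75th percentile of the processed signal ranged from 666 to 940 intensity units, and no spot was saturated. The number of arrays, and not a read depth, limits the precision. Probes were kept if they were well above background on both arrays of at least 1 group. Where a group was not well above background on any array, only a bound is printed as "at least N-fold". It sets the mean of the brighter group against the mean of the lowest signal among probes well above background, or of the probe's own signal if higher, on each array of the dimmer group.

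Probes were named through their accession where the RefSeq gene table (assembly GRCm38.p6, used for names only) held it. This was so for 22951 probes, of which 5141 received an updated symbol. The remaining 18223 kept the name of the array design. Probe coordinates are those of the scanner files, on the mouse build mm7. A gene was represented by its probe of highest mean signal, which gave 20663 genes tested. Among the genes named below, Actl6a, Dhcr7, Heyl and Itpr2 have kept probes of opposite sign in at least 1 knockdown. Probes for Zscan4, Usp17l and Tcstv genes can also bind near-identical copies, so their signals may belong to any member of the family.

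Log2 levels of all 10 arrays were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with data.table (version 1.17.8) for reading, and with group as the only term. The 5 groups shared the estimate of the spread, with 5 residual degrees of freedom, 2.23 prior degrees of freedom and a prior variance of 0.0367. Each knockdown was compared with NT, and the 6 pairs of knockdowns were compared with each other. P-values are two-sided and were adjusted by Benjamini-Hochberg over the 20663 genes of a comparison. Genes are called at an adjusted p under 0.05. Errors (±) of log2 fold changes are standard errors of this fit, with n = 2 arrays in each group. Overlaps between knockdowns are given beside 100 simulations of unchanged groups set against the same simulated NT arrays. They are also given beside the overlap of independent lists of the same lengths.

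The 18 gene lists were INO80 complex, pluripotency, primed epiblast, neuroectoderm, primitive streak and mesoderm, endoderm, trophectoderm, 2-cell-like, p53 targets, interferon response, fibroblast feeder, DNA replication and cell cycle, integrated stress response, cholesterol biosynthesis, glycolysis and hypoxia, Hox genes, germline, and ribosomal proteins. They were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the 18 lists of a comparison. Camera with an estimated correlation, and fry, which asks whether the members of a list move on balance in a given direction and does not compare it with other genes, were run beside it. For the fibroblast feeder list in the Ino80 knockdown the estimated correlation was -0.0015, below the preset. The unadjusted camera p still rose from 0.0245 to 0.0516 with it. A call lost with an estimated correlation is therefore not by itself a sign of correlated members. Members were counted over all genes tested and, separately, adjusted over the list alone. The naming rule picked the 4 targets and the INO80 complex list, the 10 largest rises and falls against NT and the 4 largest between knockdowns among called genes whose arrays did not overlap, and up to 4 members per list by adjusted p. Genes called in the same direction in all 4 knockdowns were to be named too. Where none was called, the 3 genes with the smallest p in each direction are named as values that did not pass. For all 4 knockdowns together, the p of a gene was the largest of its unadjusted p-values against NT. The text names part of the genes so picked, and says of genes outside the rule that they are.

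The fit and the list tests were tested on simulated data with 200 changed genes, 50 of each size, among the 20663. In the simulated comparison of Ino80 with NT, 88% of genes changed by 2 on the log2 scale and 34% of those changed by 1 were recovered. In that of Ino80e with NT these shares were 90% and 44%. Of 20463 unchanged genes, 8 and 11 were called in these simulated comparisons. The simulated noise was independent, had the same spread in every group and held no slide effect. These shares and counts therefore need not hold for the real arrays.

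Per the file headers, the 3 slides were scanned separately. The NT arrays lay alone on slide 1, the Ino80 and Ino80b arrays on slide 2, and the Ino80c and Ino80e arrays on slide 3. Slide and knockdown can therefore not be told apart in any comparison with NT or between knockdowns on different slides. Only Ino80 against Ino80b and Ino80c against Ino80e lie within a slide. Alternatives were normexp background correction, quantile normalization, median centring, other filters on dim probes, the mean of a gene's probes, the authors' deposited table, other fits and the omission of each array in turn.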

Results

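Expression was profiled in J1 mouse embryonic stem cells depleted of 1 of 4 subunits of INO80, a chromatin remodelling complex that slides nucleosomes along DNA with the energy of ATP. The cells were transfected with siRNAs and collected 96 hours later. Ino80 encodes the ATPase of the complex, and Ino80b, Ino80c and Ino80e encode accessory subunits. There were 5 groups with 2 arrays each: NT and the 4 knockdowns. By the title of the series, the question was how the complex takes part in the regulation that keeps these cells self-renewing. Between 27334 and 32512 of 41174 probes were well above background on an array, the fewest on Ino80e replicate 2 and the most on Ino80 replicate 1. Across genes, which are not independent replicates, log2 levels of the 2 arrays of a group correlated with r = 0.987 in NT and between 0.990 and 0.993 in the knockdowns. The median of all genes was higher in each knockdown than in NT, by 0.17 (Ino80), 0.13 (Ino80b), 0.25 (Ino80c) and 0.19 (Ino80e) on the log2 scale, a shift that depends on the scaling. Medians of gene lists are therefore given relative to the median of all genes, whereas fold changes of single genes carry the shift.

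**Figure D1:**
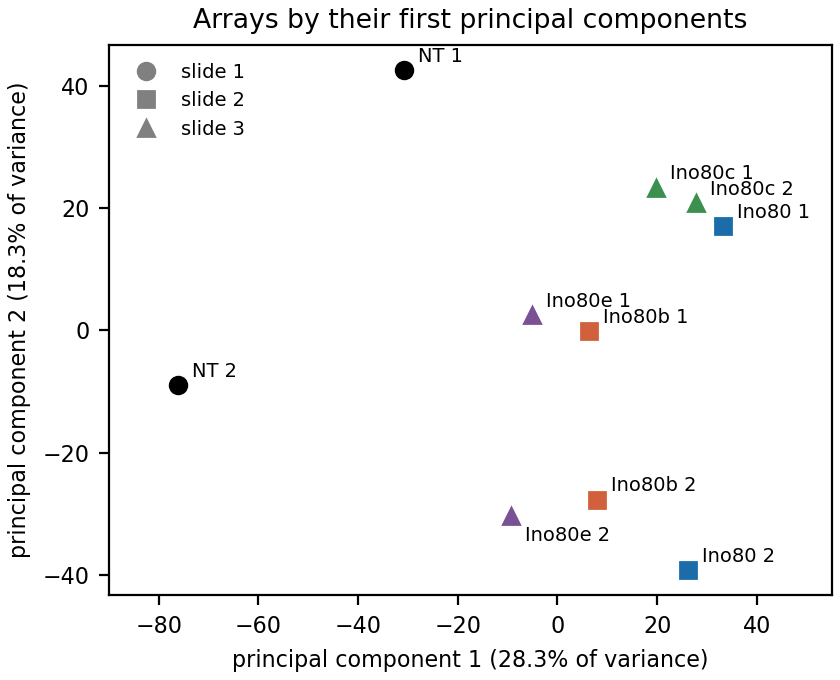
The first principal components of the log2 levels of all 20663 genes, in component units, with 1 point per array, the colour giving the group and the shape the slide. Component 1 held 28.3% of the variance. The NT arrays, alone on slide 1, lay at -30.8 and -76.2 on it and the knockdown arrays at -9.31 to 33.2. The NT arrays lay further from each other on it than NT replicate 1 lay from the nearest knockdown array.

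Each siRNA was accompanied by a lower level of its own target. Ino80 RNA fell to 43.6% of NT in the Ino80 knockdown (log2 fold change -1.20 ± 0.13, adjusted p = 0.0041, 95% interval 35.5% to 53.7%). Ino80b RNA fell to 24.9% in the Ino80b knockdown (-2.0 ± 0.35, adjusted p = 0.028), and Ino80c RNA fell to 19.7% in the Ino80c knockdown (-2.34 ± 0.16, adjusted p = 0.0107). Ino80e RNA stood at 43.4% of NT in the Ino80e knockdown (-1.20 ± 0.28, interval 27.7% to 68.0%), which did not pass over all genes (adjusted p = 0.0815) and passed when adjusted over the 16 combinations of target and knockdown alone (adjusted p = 0.0122). Over all genes it passed with normexp background correction (-1.22, adjusted p = 0.017), in the authors' deposited table (-1.41, adjusted p = 0.0372) and with a trend and robust estimation of the prior (adjusted p = 0.0364). The other 2 probes of Ino80 gave -0.92 and -0.47, and the other probe of Ino80c gave -1.63. On build mm7 the probes used lie at chromosome 2, 119114157 to 119114216 (Ino80, named Inoc1 on the array), chromosome 6, 83149452 to 83149511 (Ino80b, Znhit4), chromosome 18, 24491086 to 24491145 (Ino80c, D030070L09Rik) and chromosome 7, 122948998 to 122949057 (Ino80e, Ccdc95).

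Ino80b RNA was also lower than NT in the knockdowns of other subunits on slide 3, at -1.11 ± 0.35 with Ino80c siRNA and -1.39 ± 0.35 with Ino80e siRNA. Neither passed over all genes (adjusted p = 0.0907 and 0.0888), and both passed over the 16 combinations alone (adjusted p = 0.0336 and 0.016). It rests on 1 probe. On the probes used, Ino80 and Ino80e RNA passed neither test outside their own knockdowns. The other 2 probes of Ino80 disagreed, with 0.30 and 0.96 with Ino80b siRNA, -0.29 and 0.59 with Ino80c siRNA and -0.80 and 0.08 with Ino80e siRNA. Ino80c RNA was higher in the Ino80e knockdown over the 16 combinations alone (0.52 ± 0.16, adjusted p = 0.0324), but the other probe of Ino80c gave 0.01 there. The call of Ino80b in its own knockdown was lost without NT replicate 2 (adjusted p = 0.121), without either Ino80b array (0.1 and 0.187), without an Ino80c array (0.0583 for each) and without an Ino80e array (0.0522 for each). That of Ino80c was lost without either Ino80c array (0.0776 and 0.0732), and with only the 4 arrays compared, none of the 3 calls passed (0.117, 0.142 and 0.146).

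**Figure D2:**
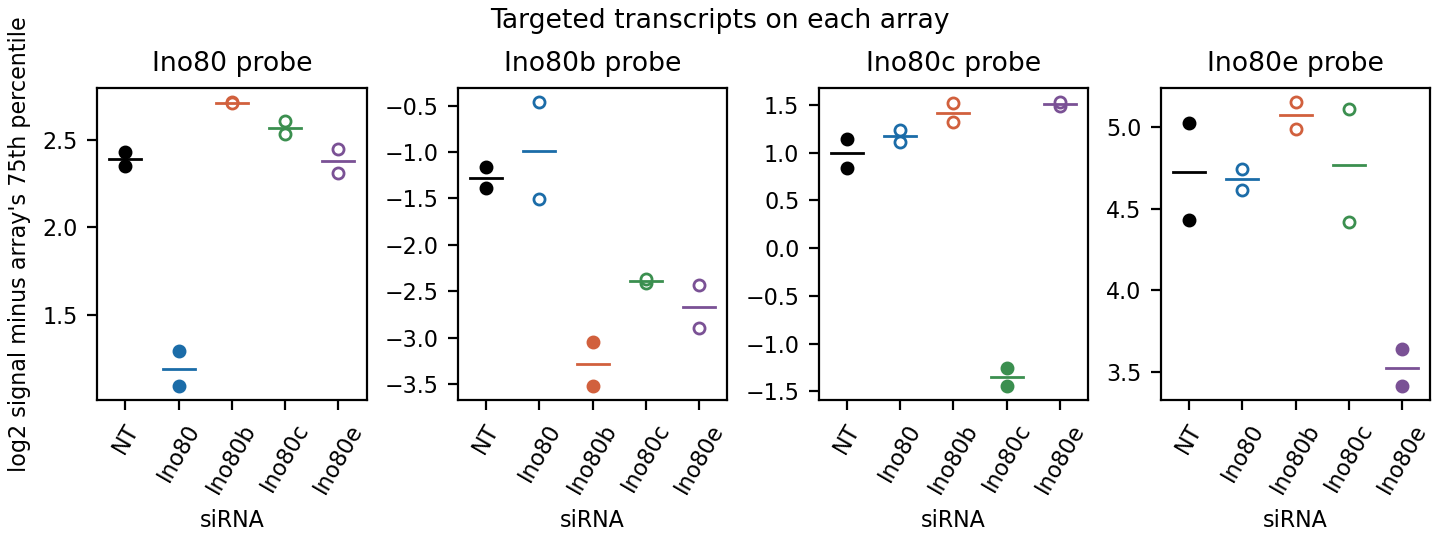
Log2 signal of the probes for the 4 targeted transcripts, minus the 75th percentile of the array, with 1 point per array and a bar at the mean of each group of 2 arrays. Filled points mark NT and the knockdown of the transcript itself, whose arrays lie below both NT arrays in every panel, and Ino80b is also below NT on the Ino80c and Ino80e arrays.

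In the Ino80 knockdown, members of the pluripotency and endoderm lists fell and members of the 2-cell-like list rose. Tfcp2l1, a transcription factor of naive pluripotent cells, fell 5.98-fold (log2 fold change -2.58 ± 0.16), Tbx3 fell 5.83-fold (-2.54 ± 0.32), Tet2, which oxidises 5-methylcytosine, fell 3.59-fold (-1.84 ± 0.17), and Nanog fell 2.55-fold (-1.35 ± 0.20). Gata6, the transcription factor that specifies primitive endoderm, fell 8.71-fold (-3.12 ± 0.19) on the brightest of its 3 probes, which ranged from -3.12 to -0.35. Bmp4, a secreted growth factor, fell 6.38-fold (-2.67 ± 0.17). Zscan4c, a marker of the brief 2-cell-like state of embryonic stem cells, rose 7.13-fold (2.83 ± 0.22). Each of these 7 genes had n = 2 arrays per group and an adjusted p between 0.00153 and 0.011 by limma. On build mm7 the probes for Nanog, Gata6, Bmp4 and Zscan4c lie at chromosome 6, 122750894 to 122750953, chromosome 18, 11291591 to 11291649, chromosome 14, 41704207 to 41704266, and chromosome 7, 9713271 to 9713330.

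Of 20663 genes, 2531 were called against NT, 1547 higher and 984 lower, 1174 of them at least 2-fold. Among the largest rises were Usp17la (2.83 ± 0.25), Creb5 (2.35 ± 0.40), the zinc transporter gene Slc39a8 (2.30 ± 0.18) and Dcn, which encodes the matrix proteoglycan decorin (2.30 ± 0.32). Lce1d, Olfr738, Adamts6, Olah and Arts1 were not well above background in NT and rose at least 3.06-fold, 2.97-fold, 2.67-fold, 2.52-fold and 1.69-fold. Among picked genes given with more than a bound, Slc11a1, a metal ion transporter of macrophages, fell most (-3.57 ± 0.28). Clca3b, Gpr83, Slc4a7, Nkx6-3 and the drug efflux pump gene Abcb1a fell by between -3.24 and -3.32. Pdgfra, the receptor for platelet-derived growth factor, was not well above background after knockdown and fell at least 9.27-fold, and Kcnk2, Zscan5b and Islr2 likewise fell at least 3.61-fold, 3.86-fold and 2.12-fold. The count was 832 without NT replicate 2, 560 without Ino80 replicate 2 (276 higher and 284 lower), 1525 without either Ino80b array, 1613 without either Ino80c array, 1544 without either Ino80e array and 0 with only the 4 arrays compared. Here a lone array was assumed to vary like the other groups. Of the 77 called genes picked by the naming rule, 48 and 41 were still called without NT replicate 2 and Ino80 replicate 2.

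Of 41 pluripotency genes, 17 fell, 1 rose and 23 were not called. Adjusted over the list alone, 22 were lower and 1 higher. The median of the list lay -0.77 below that of all genes on the log2 scale (camera, adjusted p = 1.3e-12). It was lost with an estimated correlation (adjusted p = 0.128 with an estimated correlation), and fry gave an adjusted p of 0.00284 (raw median -0.61). The exception was Dppa3, a maternal factor that protects DNA methylation, which rose (1.42 ± 0.37). Of 29 endoderm genes, 13 fell and 1 rose, with 13 lower and 4 higher when adjusted over the list alone (median relative to all genes -0.49, camera adjusted p = 1.9e-06). The value was adjusted p = 0.128 with an estimated correlation. Besides Gata6 and Pdgfra, the basement membrane genes Lama1 (-1.99 ± 0.18) and Col4a2 (-1.92 ± 0.15) fell. Of 9 genes of the 2-cell-like list, 6 rose and none fell, with 8 higher and 1 lower over the list alone (median 1.12, camera adjusted p = 0.000483, adjusted p = 0.292 with an estimated correlation). Tcstv1 (2.09 ± 0.33) and Tcstv3 (1.97 ± 0.26) were among them. Of 31 p53 targets, Pltp (-1.85 ± 0.38) and Gdf15 (-1.42 ± 0.36) fell and none rose, with 1 lower over the list alone. The p53 list lay below all genes (-0.35, camera adjusted p = 0.0123, adjusted p = 0.258 with an estimated correlation), and its call was lost without NT replicate 1 (0.059) and without Ino80 replicate 1 (0.0956).

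The other lists did not pass camera in the Ino80 knockdown (adjusted p from 0.0805 to 0.925), though single members were called. Of 19 primed epiblast genes, 6 rose and 1 fell, with 6 and 2 over the list alone. Otx2 (1.17 ± 0.13), Sall2 (1.14 ± 0.13) and the neural transcription factor gene Pou3f1 (1.52 ± 0.22) rose, and Foxa2, which also stands in the endoderm list, fell (-1.99 ± 0.32). Of 32 trophectoderm genes 7 rose and 6 fell, among them Bmp8b (1.68 ± 0.12) and the connexin gene Gjb5 (-2.40 ± 0.14), with 7 and 7 over the list alone. Of 29 genes of primitive streak and mesoderm 2 rose and 6 fell, with 2 and 8 over the list alone, and of 29 neuroectoderm genes 1 rose and 4 fell, with 3 and 4. Of 34 interferon response genes 3 rose and 4 fell, with 8 and 4 over the list alone. Oas1a (-2.25 ± 0.20) and Ddx58, a sensor of viral RNA (-1.34 ± 0.19), fell, and Irf1 rose (1.33 ± 0.21). Of 33 germline genes 6 rose and 2 fell, with 6 and 5 over the list alone, the rises including Tdrd1 (1.68 ± 0.17) and Spo11, the meiotic nuclease (2.00 ± 0.33), and the falls Piwil4 (-1.69 ± 0.19).

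Of the 29 fibroblast feeder markers tested, 7 rose and none fell, over all genes and over the list alone (median relative to all genes 0.35, camera adjusted p = 0.0805). Fry, which does not compare the list with other genes, gave an adjusted p of 0.00268 (raw median 0.52). Dcn, Tagln (1.43 ± 0.15), Twist2 (1.11 ± 0.19) and Col5a1 (0.78 ± 0.11) were among those that rose. In the INO80 complex list of 15 genes, Uchl5 rose (0.63 ± 0.15) and Actl6a fell beside Ino80 itself (-0.47 ± 0.12), although another probe of Actl6a gave 0.10. The counts over the list alone were 1 and 2. Of 30 cholesterol biosynthesis genes 5 rose and 1 fell (6 and 1 over the list alone), of 41 genes of DNA replication and cell cycle 2 rose and 2 fell (0 and 1), and of 38 genes of the integrated stress response 1 rose and 2 fell (0 and 2). Ccnd3, a D-type cyclin gene, fell (-1.24 ± 0.14). In the lists of glycolysis and hypoxia (31 genes) and ribosomal proteins (75 genes), Slc16a3 and Rps26 rose and no member fell, with 0 called over either list alone. None of 24 Hox genes was called, over all genes or over the list alone.

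**Figure D3:**
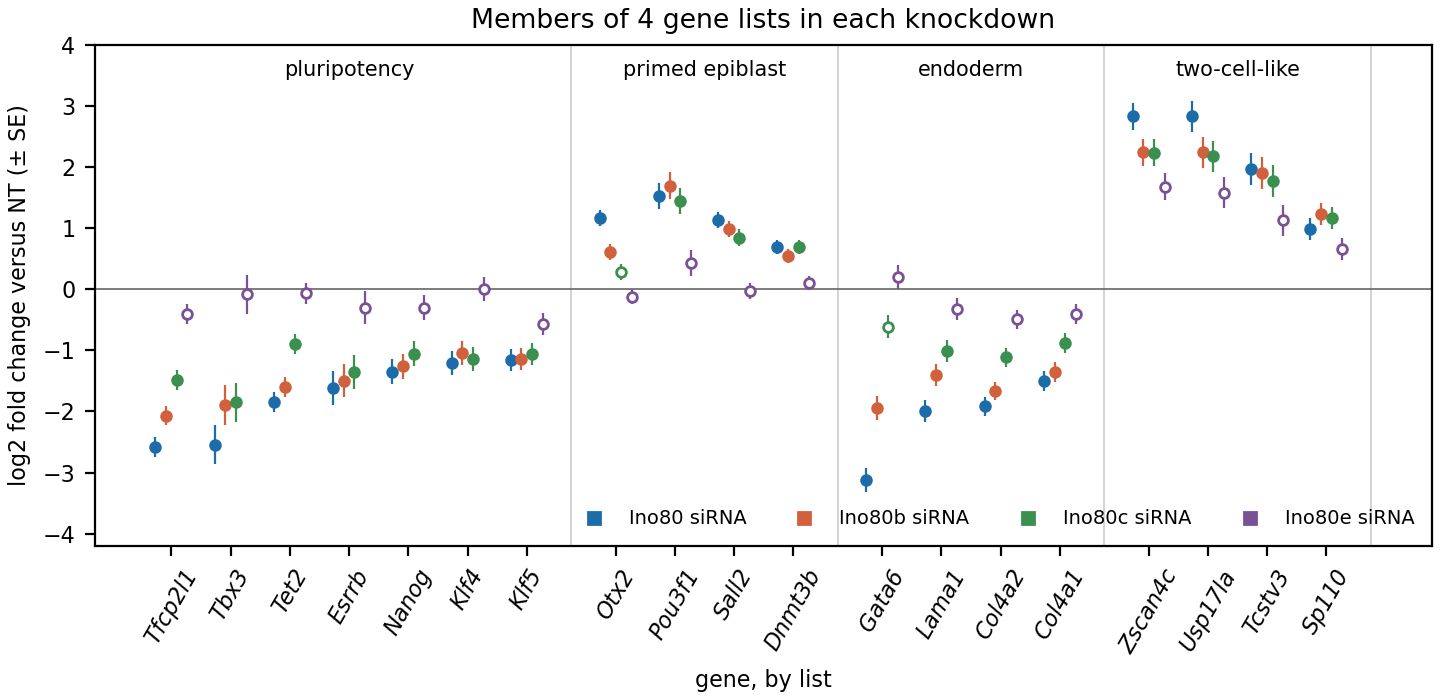
Log2 fold change against NT of members of 4 gene lists in the knockdowns of Ino80, Ino80b, Ino80c and Ino80e, with points at the fitted value, bars of ± 1 standard error and n = 2 arrays per group. Filled points passed an adjusted p of 0.05 and open points did not. The members were chosen for display after their values were seen. All Ino80e points are open, and the pluripotency points of the other knockdowns lie between -0.90 and -2.58.

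In the Ino80b knockdown Tfcp2l1 fell 4.19-fold (log2 fold change -2.07 ± 0.16), Tet2 3.03-fold (-1.60 ± 0.17), Nanog 2.40-fold (-1.26 ± 0.20) and the Krüppel-like factor gene Klf5 2.21-fold (-1.15 ± 0.18). Gata6 fell 3.85-fold (-1.94 ± 0.19, with its 3 probes between -1.94 and -0.23) and Bmp4 4.78-fold (-2.26 ± 0.17), whereas Zscan4c rose 4.73-fold (2.24 ± 0.22) and Pou3f1 3.24-fold (1.70 ± 0.22). These 8 genes had an adjusted p between 0.0085 and 0.0231. In all, 1325 genes were called, 773 higher and 552 lower, 621 of them at least 2-fold. Of the calls, 58.3% were higher against 68.8% with normexp background correction and 38.0% in the authors' deposited table. Among the largest rises were Usp17la (2.24 ± 0.25), the brain fatty acid binding protein gene Fabp7 (2.19 ± 0.28), Rasgrp3 (2.12 ± 0.42), Pnlip (2.00 ± 0.31), Olfr701 (2.18 ± 0.40) and Olfr149 (2.12 ± 0.31). Akr1d1 and Kera, which were not well above background in NT, rose at least 2.56-fold and 2.99-fold. Arts1 was called higher while not well above background in either group, so it has no fold. Among picked genes given with more than a bound, Slc11a1 (-3.58 ± 0.28), Slc4a7 (-3.50 ± 0.68), Septin1 (-2.89 ± 0.28), Clca3b (-2.60 ± 0.38) and Srgn, a proteoglycan gene of blood cells (-2.55 ± 0.52), fell most. Gpr149, Islr2, Prdm6, Zscan5b and Tbx22 fell at least 1.91-fold, 1.69-fold, 2.35-fold, 3.08-fold and 1.43-fold. The count was 2856 without NT replicate 1, 36 without NT replicate 2 (7 higher and 29 lower), 0 and 1 without Ino80b replicate 1 and 2, 403 without either Ino80c array, 363 without either Ino80e array and 0 with only the 4 arrays compared. Of the 60 called genes picked by the naming rule, 7 were still called without NT replicate 2.

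Of 41 pluripotency genes, 11 fell and none rose in the Ino80b knockdown, with 14 lower when adjusted over the list alone. The list median was -0.38 relative to all genes (camera adjusted p = 5.2e-07, adjusted p = 0.248 with an estimated correlation). Of 29 endoderm genes, 10 fell, with 12 lower and 4 higher over the list alone, Col4a2 (-1.67 ± 0.15), Col4a1 (-1.36 ± 0.16) and Pdgfra (-1.78 ± 0.20) among them (median -0.33, camera adjusted p = 0.00019, adjusted p = 0.248 with an estimated correlation). Of 9 genes of the 2-cell-like list 6 rose, and 7 over the list alone, including Tcstv3 (1.90 ± 0.26) and Sp110 (1.24 ± 0.18), with a median of 1.51 (camera adjusted p = 8.7e-05, adjusted p = 0.262 with an estimated correlation). Of 19 primed epiblast genes, 5 rose and none fell, and 6 rose over the list alone, among them Sall2 (0.99 ± 0.13), Otx2 (0.61 ± 0.13) and the DNA methyltransferase gene Dnmt3b (0.55 ± 0.11). That list passed camera (median 0.37, adjusted p = 0.00439, adjusted p = 0.248 with an estimated correlation), and not without NT replicate 1 (0.0585). Of 75 ribosomal protein genes only Rps26 was called (0.64 ± 0.12) and none over the list alone, while the list as a whole lay above other genes (median 0.09, camera adjusted p = 0.00163, adjusted p = 0.903 with an estimated correlation). Its sign turned with quantile normalization (-0.042). Its call was also lost in the authors' deposited table and without Ino80b replicate 2.

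The integrated stress response list was lower in the Ino80b knockdown (median -0.26, camera adjusted p = 0.049, adjusted p = 0.903 with an estimated correlation). Ppp1r15a was called lower (-0.83 ± 0.15) among 38 genes, and 1 over the list alone. Its call was lost without NT replicate 2, without either Ino80 array, without Ino80b replicate 1, with array weights and with only the arrays compared, and its adjusted p ranged from 0.00196 to 0.97 over the alternatives. The cholesterol biosynthesis list was higher (median 0.25, camera adjusted p = 0.049, adjusted p = 0.903 with an estimated correlation). Dhcr7 (0.76 ± 0.14) and Sc5d (0.68 ± 0.14), which act late in the pathway, were called among 30 genes, with 7 higher and 1 lower over the list alone. Another probe of Dhcr7 gave -0.52, and the call of the list held in 6 of 21 alternatives. Other lists did not pass, and their called members included Gjb5 (-1.98 ± 0.14), Lgals3 (-1.91 ± 0.18), Bmp8b (1.16 ± 0.12), Ddx58 (-1.32 ± 0.19), Isg15 (1.68 ± 0.25), Ccnd3 (-1.17 ± 0.14), the stem cell factor receptor gene Kit (-1.79 ± 0.37) and Fas (0.72 ± 0.11). Of 29 fibroblast feeder markers, Twist2 (1.08 ± 0.19) and Dcn (1.40 ± 0.32) rose, over all genes and over the list alone (median 0.16, camera adjusted p = 0.192). Their raw median was 0.29, with a fry adjusted p of 0.0116.

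In the Ino80c knockdown Bmp4 fell 5.28-fold (log2 fold change -2.40 ± 0.17), Tbx3 3.60-fold (-1.85 ± 0.32), Tfcp2l1 2.80-fold (-1.49 ± 0.16), Klf4 2.20-fold (-1.14 ± 0.20) and Klf5 2.08-fold (-1.06 ± 0.18), while another probe of Klf5 gave -0.22. Zscan4c rose 4.71-fold (2.23 ± 0.22), Usp17la, of the same 2-cell-like list, 4.52-fold (2.18 ± 0.25) and Pou3f1 2.72-fold (1.44 ± 0.22). Their adjusted p lay between 0.0134 and 0.029, with n = 2 arrays per group by limma. There were 1297 calls, 969 higher and 328 lower, 674 of them at least 2-fold. Of the calls, 74.7% were higher against 54.6% with quantile normalization and 27.9% in the authors' deposited table. Hoxb2 rose (2.43 ± 0.42). Heyl, a target of Notch signalling, and Olfr1471 were called higher, but their NT means of -7.76 and -7.32 lay below the lowest levels counted as well above background (-6.47 and -6.50), so no fold is given. Another probe of Heyl gave -0.07. Casc1, Ly86, Acot5, Olfr435, Olfr533, Odf1 and Dhrs9, not well above background in NT, rose at least 5.60-fold, 4.30-fold, 2.77-fold, 2.75-fold, 2.71-fold, 2.05-fold and 1.90-fold. The sign of Dhrs9 turned without the filter on dim probes (-0.31). Besides Bmp4 and Ino80c, the largest falls were those of Slc11a1 (-3.27 ± 0.28), Slc4a7 (-3.08 ± 0.68), Septin1 (-2.79 ± 0.28), Parvb (-2.13 ± 0.19), Pgc (-2.12 ± 0.48) and Git1 (-1.99 ± 0.36), with Gpr149 and Islr2 at least 1.96-fold and 1.74-fold lower. The count was 3142 without NT replicate 1, 11 without NT replicate 2 (5 higher and 6 lower), 1 and 0 without Ino80c replicate 1 and 2, 297 without either Ino80b array, 178 without either Ino80e array and 0 with only the 4 arrays compared. Of the 61 called genes picked by the naming rule, 6 were still called without NT replicate 2.

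Of 41 pluripotency genes, 9 fell and none rose in the Ino80c knockdown, with 14 lower when adjusted over the list alone (median -0.44 relative to all genes, camera adjusted p = 7.9e-09, adjusted p = 0.402 with an estimated correlation). Of 9 genes of the 2-cell-like list 7 rose, and 7 over the list alone, Tcstv3 (1.78 ± 0.26) and Sp110 (1.16 ± 0.18) among them (median 1.34, camera adjusted p = 0.00137, adjusted p = 0.402 with an estimated correlation). Of 29 endoderm genes 3 fell and 2 rose, with 4 and 3 over the list alone. Col4a2 (-1.12 ± 0.15), Lama1 (-1.02 ± 0.18) and Col4a1 (-0.88 ± 0.16) stood against the liver transcription factor gene Hnf4a (1.17 ± 0.21), and another probe of Lama1 gave -0.12. The endoderm list lay below other genes (median -0.34, camera adjusted p = 0.00772, adjusted p = 0.402 with an estimated correlation), and Gata6 was not called (-0.61 ± 0.19). The raw median of that list was -0.08, and fry gave an adjusted p of 0.269. The INO80 complex list lay below other genes (median -0.34, camera adjusted p = 0.0199, adjusted p = 0.402 with an estimated correlation). Ino80c, the target itself, was its only called member, with 3 lower and 2 higher over the list alone. The list did not pass without Ino80c (14 genes, median -0.34, adjusted p = 0.0993, chosen after the data were seen), without NT replicate 1 or without Ino80c replicate 2. Of 30 cholesterol biosynthesis genes, Acat2 (-0.84 ± 0.16) and Mvk, mevalonate kinase (-0.72 ± 0.16), fell, over all genes and over the list alone (median -0.24, camera adjusted p = 0.0199, adjusted p = 0.664 with an estimated correlation). That call was lost without NT replicate 2. Of 31 genes of glycolysis and hypoxia none was called, over all genes or over the list alone, while the list lay below other genes (-0.15, camera adjusted p = 0.0246, adjusted p = 0.698 with an estimated correlation). That call was lost with quantile normalization, without NT replicate 2 and without Ino80c replicate 1. The raw medians of the cholesterol and glycolysis lists were 0.01 and 0.10, above 0, and their means -0.07 and -0.08, below it.

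The remaining lists did not pass camera in the Ino80c knockdown. Of 33 germline genes 7 rose and 1 fell, and 8 and 1 over the list alone, with Spo11 (2.31 ± 0.33), Taf7l (1.31 ± 0.18) and Tdrd1 (1.19 ± 0.17) higher. The p53 targets Fas, a death receptor gene (1.01 ± 0.11), Pmaip1 (0.86 ± 0.16) and Trp53inp1 (0.66 ± 0.14) rose and none of 31 fell, with 5 and 1 over the list alone. Of 19 primed epiblast genes 4 rose, and 7 over the list alone, among them Sall2 (0.85 ± 0.13), Dnmt3b (0.70 ± 0.11) and Dnmt3a (0.95 ± 0.22). Bmp8b (1.35 ± 0.12) and Rhox6 (1.21 ± 0.14) rose and Gjb5 (-1.40 ± 0.14) fell in the trophectoderm list, which had 6 higher and 5 lower of 32. Of 29 fibroblast feeder markers, Dcn (2.08 ± 0.32), Twist2 (1.15 ± 0.19) and Tagln (0.67 ± 0.15) rose, over all genes and over the list alone (median 0.11, camera adjusted p = 0.14). Their raw median was 0.36, with a fry adjusted p of 0.00464.

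In the Ino80e knockdown no gene passed. The smallest adjusted p by limma was 0.0535, while 5899 of 20663 genes had an unadjusted p under 0.05 and 2118 an adjusted p under 0.1, of which 1590 were higher and 528 lower. The values nearest to passing included the monoamine transporter gene Slc18a2 (1.66 ± 0.16), Tifab (at least 1.77-fold higher) and Naip6 (at least 7.16-fold higher), and Calcoco1 (-1.15 ± 0.16), Ptk7 (-0.89 ± 0.13) and Gpr149 (at least 1.94-fold lower), each with an adjusted p of 0.0648. The count was 587 without NT replicate 1, 1 without either Ino80 array and 1 without Ino80e replicate 2. It was 5387 with normexp background correction, 1103 in the authors' deposited table (236 higher and 867 lower), 1701 with a trend and robust estimation of the prior and 504 with probes well above background on all 10 arrays. Genes were called too with replicate number as a block, as given below, although nothing in the labels pairs the numbers.

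Of 9 genes of the 2-cell-like list, none was called over all genes in the Ino80e knockdown and 6 were higher when adjusted over the list alone, with Zscan4c at 1.68 ± 0.22, Usp17la at 1.58 ± 0.25, Tdpoz1 at 1.73 ± 0.34 and Tcstv3 at 1.13 ± 0.26. The list lay above other genes (median 0.74, camera adjusted p = 0.0197, adjusted p = 0.703 with an estimated correlation), and its call was lost with normexp background correction, without either NT array and without Ino80e replicate 1. Of 41 pluripotency genes none was called, over all genes or over the list alone. The list lay below other genes (median -0.23, camera adjusted p = 0.0148, adjusted p = 0.703 with an estimated correlation), a call that was lost without NT replicate 2 (0.283) and without Ino80e replicate 1 (0.109). Foxd3 was at -0.51 ± 0.12, Sall4 at -0.58 ± 0.14, Utf1 at -0.83 ± 0.24 and Dppa3 at 1.32 ± 0.37, and the raw median of the list was -0.04. The 75 ribosomal protein genes lay above other genes with none called (median 0.07, camera adjusted p = 0.00543, adjusted p = 0.988 with an estimated correlation). Their sign turned with quantile normalization (-0.054). The call was also lost with normexp background correction, in the authors' deposited table, without NT replicate 1 and without Ino80e replicate 2. Rpl21 was at 0.51 ± 0.12 and Rpl35 at 0.44 ± 0.13. The 29 fibroblast feeder markers had a median of -0.17 relative to all genes (camera adjusted p = 0.198), with none called over all genes and 1 higher and 1 lower over the list alone. Their raw median was 0.02, and fry, which does not compare the list with other genes, gave an adjusted p of 0.807.

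No gene was called in all 4 knockdowns, since none was called with Ino80e siRNA. Genes of the same sign in all 4 were therefore ranked by the largest of their 4 unadjusted p-values. By the smallest such p, Zscan4c, Bmp8b and the neuronal kinase gene Brsk2 were higher in all 4. Brsk2 was at 1.66, 1.28, 1.09 and 1.04 (each ± 0.15) in the Ino80, Ino80b, Ino80c and Ino80e knockdowns. Calcoco1 was lower in all 4, at -1.04, -1.01, -1.19 and -1.15 (each ± 0.16), as were Septin1 (-3.23, -2.89, -2.79 and -1.63, each ± 0.28) and Gpr149. In the mean of the 4 knockdowns against NT, 2628 genes were higher and 1150 lower. The knockdowns of Ino80, Ino80b and Ino80c shared 359 genes called higher and 227 called lower.

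Between Ino80 and Ino80b, 585 genes were called higher in both and 444 lower in both, where independent lists of the same lengths would share 57.9 and 26.3. Only Kera was called in opposite directions, as seen after the calls were made, and it was not well above background in NT or in the Ino80 knockdown. Ino80 and Ino80c shared 498 and 267 (independent lists, 72.5 and 15.6), with 6 genes opposite, and Ino80b and Ino80c shared 449 and 238 (36.3 and 8.76), with 0 opposite. In 100 simulations of unchanged groups against the same simulated NT arrays, at most 1 gene was shared in any pair. These simulations had independent noise, of the same spread in every group, and no slide effect. Across genes, log2 fold changes correlated with r = 0.74 for Ino80 and Ino80b, 0.71 for Ino80 and Ino80c and 0.68 for Ino80b and Ino80c, beside 0.50 in the simulations for each. With Ino80e, r was 0.57 for Ino80, 0.62 for Ino80b and 0.65 for Ino80c. The covariance of Ino80 and Ino80b was 0.25 beside a simulated 0.05, a difference of 0.20, and with Ino80e the differences were 0.13 (Ino80), 0.12 (Ino80b) and 0.13 (Ino80c). Part of the excess may come from the shared NT arrays, which are too few to be split. An effect of the slide on which NT lay alone would also be shared, and neither the simulations nor the independent lists include it. Over the 6 pairs the shared calls in the same direction summed to 2481, and to 7533 without NT replicate 1, 48 without NT replicate 2, 1286 without Ino80 replicate 2, 206 without either Ino80b array, 350 without either Ino80c array, and 555 and 558 without Ino80e replicate 1 and 2.

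Within slide 2, the Ino80 and Ino80b knockdowns differed in 14 genes, 2 higher and 12 lower with Ino80 siRNA. The forkhead factor gene Foxa2, which acts in endoderm, was lower with Ino80 siRNA (-3.34 ± 0.32, adjusted p = 0.0301), as were the growth factor gene Fgf18 (-2.62 ± 0.27, adjusted p = 0.0425) and Ino80 itself. Kera and Akr1d1 were at least 2.69-fold and 2.30-fold lower, and Lce1d was at least 2.19-fold higher, while the other higher call was a clone without a gene symbol. The endoderm list was lower with Ino80 than with Ino80b siRNA (median relative to all genes -0.18, Foxa2 called, 3 lower over the list alone, camera adjusted p = 0.000525, adjusted p = 0.239 with an estimated correlation). So was the pluripotency list, with no member called over all genes or over the list alone (median -0.18, camera adjusted p = 2.8e-05, adjusted p = 0.383 with an estimated correlation). The p53 list was lower too, with 0 called and 2 lower over the list alone (median -0.23, camera adjusted p = 5.9e-07, adjusted p = 0.123 with an estimated correlation). The ribosomal protein list (-0.20, camera adjusted p = 4.7e-11, adjusted p = 0.523 with an estimated correlation) and the DNA replication and cell cycle list (-0.12, adjusted p = 0.033, and adjusted p = 0.522 with an estimated correlation) were lower and the integrated stress response list (0.30, adjusted p = 0.00349, and adjusted p = 0.664 with an estimated correlation) and the glycolysis and hypoxia list (0.17, adjusted p = 0.033, and adjusted p = 0.825 with an estimated correlation) higher, with 0 members called over all genes or over the list alone. The ribosomal call was lost with quantile normalization, and the glycolysis list turned sign without Ino80 replicate 2 (-0.092) and did not pass without Ino80b replicate 1. The stress response call was lost without Ino80 replicate 2 and without Ino80b replicate 1, and the replication call held in 15 of 22 alternatives. The count of 14 was 9 without either NT array, 6 without Ino80 replicate 1 (5 higher and 1 lower), 2 without Ino80 replicate 2 (2 higher and 0 lower), 0 and 1 without Ino80b replicate 1 and 2, 0 without either Ino80c array, 6 without either Ino80e array and 0 with only the arrays of the slide.

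Within slide 3, the Ino80c and Ino80e knockdowns differed in 7 genes. Bmp4 was lower with Ino80c than with Ino80e siRNA (-1.90 ± 0.17, adjusted p = 0.0337), as were Ankrd33b (-1.79 ± 0.16), Ino80c (-2.86 ± 0.16) and a clone without a gene symbol. Igdcc4 (1.36 ± 0.13), Olfr533 (at least 1.98-fold) and Dhrs9 were higher. The Ino80e mean of Dhrs9 (-7.96) lay below the lowest levels counted as well above background there (-6.18 and -5.87), so no fold is given. Its difference was -0.99 without the filter on dim probes. With Ino80c siRNA the pluripotency list was lower (median relative to all genes -0.27, 7 lower and 1 higher over the list alone, camera adjusted p = 1.7e-05, adjusted p = 0.238 with an estimated correlation). So was the endoderm list (-0.21, 7 lower over the list alone, adjusted p = 0.000208, and adjusted p = 0.12 with an estimated correlation). The primed epiblast list was higher (0.32, 7 higher over the list alone, adjusted p = 8.6e-06, and adjusted p = 0.0557 with an estimated correlation). Higher too were the 2-cell-like list (0.58, 0 over the list alone, adjusted p = 0.00428, and adjusted p = 0.387 with an estimated correlation) and the fibroblast feeder list (0.50, 6 higher over the list alone, adjusted p = 2.2e-05, and adjusted p = 0.0557 with an estimated correlation). No member of these 5 lists was called over all genes, and the 2-cell-like call was lost without Ino80c replicate 1 (0.0788). The p53 list was higher as well (0.18, 0 called and 7 over the list alone, adjusted p = 0.000392, and adjusted p = 0.12 with an estimated correlation). Lower with Ino80c siRNA were the ribosomal protein list (-0.12, adjusted p = 2.2e-05, and adjusted p = 0.623 with an estimated correlation), the glycolysis and hypoxia list (-0.30, adjusted p = 0.000178, and adjusted p = 0.445 with an estimated correlation) and the cholesterol biosynthesis list (-0.26, adjusted p = 0.00046, and adjusted p = 0.402 with an estimated correlation). The lists of DNA replication and cell cycle (-0.12, adjusted p = 0.00622, and adjusted p = 0.387 with an estimated correlation) and of the integrated stress response (-0.16, adjusted p = 0.0407, and adjusted p = 0.655 with an estimated correlation) were lower too. The Hox list was higher (0.20, adjusted p = 0.00794, and adjusted p = 0.445 with an estimated correlation). No member of these 6 lists was called over all genes, and over the list alone only 1 replication gene was, lower. The ribosomal, replication and Hox calls were lost with quantile normalization, the last pair also with normexp background correction and without Ino80c replicate 2, and the stress response call held in 15 of 22 alternatives. The count of 7 was 17 without either NT array, 1 without either Ino80b array, 2 and 0 without Ino80c replicate 1 and 2, 0 without either Ino80e array and 0 with only the arrays of the slide.

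Comparisons across slides 2 and 3 cannot tell slide and siRNA apart. In them, the Ino80 knockdown differed from the Ino80e knockdown in 637 genes (233 higher and 404 lower). It differed from the Ino80c knockdown in 215 (28 and 187). In the authors' deposited table the balance turned, with 1157 higher and 504 lower than with Ino80e siRNA, and 574 and 277 against Ino80c siRNA. Ino80b differed from Ino80e in 144 (51 and 93) and from Ino80c in 6 (3 and 3). Among the largest differences from Ino80e, Srgn (-4.07 ± 0.52 for Ino80 and -3.56 ± 0.52 for Ino80b) and the endocytic receptor gene Cubn (-3.93 ± 0.29 and -3.02 ± 0.29) were lower, as was Tfec for Ino80b (-3.09 ± 0.31). Pdgfra was at least 13.6-fold lower with Ino80 than with Ino80e siRNA and at least 7.13-fold lower than with Ino80c siRNA, and Naip6 was at least 5.14-fold lower with Ino80b than with Ino80e siRNA. Lce1d (at least 2.23-fold), Olah (at least 1.84-fold), Foxd4 and Adamts6 were higher with Ino80 than with Ino80e siRNA, and the last pair turned sign with normexp background correction (-0.025 and -0.070). Rhox5, an X-linked homeobox gene, was lower with Ino80 than with Ino80c siRNA (-3.11 ± 0.21), while Slc39a8 (1.75 ± 0.18) and Stmn4 (1.63 ± 0.20) were higher. Fabp7 (2.30 ± 0.28) and Itpr2 (2.23 ± 0.16) were higher with Ino80b than with Ino80e siRNA. Akr1d1 and Kera were at least 1.88-fold and 2.20-fold higher with Ino80b than with Ino80c siRNA, and Dhrs9 was at least 1.36-fold lower, with the sign turned (0.11) without the filter on dim probes.

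Of 29 endoderm genes, 11 were lower with Ino80 than with Ino80e siRNA and none higher, with 15 lower and 1 higher over the list alone (median relative to all genes -0.44, camera adjusted p = 2.0e-06, adjusted p = 0.0606 with an estimated correlation). With Ino80b siRNA, 7 were lower than with Ino80e siRNA, with 12 and 1 over the list alone (-0.33, adjusted p = 0.000111, and adjusted p = 0.109 with an estimated correlation). Of 41 pluripotency genes, 8 were lower with Ino80 than with Ino80e siRNA, and 17 over the list alone (-0.37, adjusted p = 3.5e-08, and adjusted p = 0.143 with an estimated correlation). Primed epiblast genes were higher with Ino80b than with Ino80e siRNA, 1 over all genes and 9 over the list alone (0.53, adjusted p = 5.2e-09), and the call held with an estimated correlation (adjusted p = 0.0355). Fibroblast feeder markers were higher than with Ino80e siRNA in the Ino80 knockdown (median 0.71, 3 called and 5 over the list alone) and in the Ino80b knockdown (0.34, 0 called and 1 over the list alone), and both calls held with an estimated correlation (adjusted p = 0.0471 and 0.0355). All these list differences lie across slides, so slide and siRNA cannot be told apart in them. Against the Ino80c knockdown, 6 endoderm genes were lower with Ino80 siRNA, and 14 lower and 1 higher over the list alone (-0.42, adjusted p = 8.4e-06, and adjusted p = 0.112 with an estimated correlation). The count of 637 was 226 and 185 without Ino80 replicate 1 and 2, 280 without either Ino80b array, 310 without either Ino80c array, and 94 and 42 without Ino80e replicate 1 and 2. That of 215 was 107 and 27 without Ino80 replicate 1 and 2, 84 without either Ino80b or either Ino80e array, and 4 and 0 without Ino80c replicate 1 and 2. That of 144 was 0 and 2 without Ino80b replicate 1 and 2, 47 without either Ino80c array and 0 without either Ino80e array. That of 6 was 3 and 1 without Ino80b replicate 1 and 2, 2 and 0 without Ino80c replicate 1 and 2 and 2 without either Ino80e array.

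Besides these, primed epiblast genes (median relative to all genes 0.62, 4 higher and 1 lower, with 10 and 1 over the list alone, adjusted p = 2.9e-05, and adjusted p = 0.0606 with an estimated correlation) and 2-cell-like genes (0.87, 2 higher, with 5 over the list alone, adjusted p = 0.003, and adjusted p = 0.407 with an estimated correlation) were higher with Ino80 than with Ino80e siRNA. The cholesterol biosynthesis list (0.19, 1 higher, with 2 over the list alone, adjusted p = 0.00661, and adjusted p = 0.626 with an estimated correlation) was higher too. Lower were the ribosomal protein list (-0.20, 0 called over all genes or over the list alone, adjusted p = 2.0e-06, and adjusted p = 0.711 with an estimated correlation) and the DNA replication and cell cycle list (-0.21, 1 lower, with 1 over the list alone, adjusted p = 0.00645, and adjusted p = 0.407 with an estimated correlation). The ribosomal and replication calls were lost with normexp background correction, with quantile normalization and without Ino80 replicate 1, the replication call also in the authors' deposited table, and the cholesterol call without Ino80 replicate 2. With Ino80b siRNA, the 2-cell-like list (0.72, 0 called and 7 higher over the list alone, adjusted p = 0.000466, and adjusted p = 0.305 with an estimated correlation), the cholesterol list (0.20, 0 called and 1 higher over the list alone, adjusted p = 0.000661, and adjusted p = 0.464 with an estimated correlation) and the p53 list (0.22, 0 called over all genes or over the list alone, adjusted p = 0.00236, and adjusted p = 0.188 with an estimated correlation) were higher than with Ino80e siRNA. Lower were the pluripotency list (-0.18, 2 lower, with 7 over the list alone, adjusted p = 0.000515, and adjusted p = 0.361 with an estimated correlation), the integrated stress response list (-0.30, 0 called and 2 lower over the list alone, adjusted p = 0.0111, and adjusted p = 0.684 with an estimated correlation) and the glycolysis and hypoxia list (-0.16, 0 called and 3 lower over the list alone, adjusted p = 0.0123, and adjusted p = 0.684 with an estimated correlation). The stress response and glycolysis calls were lost with normexp background correction, without Ino80b replicate 1 and without Ino80e replicate 2, and the cholesterol call without Ino80b replicate 2.

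Against the Ino80c knockdown, cholesterol biosynthesis genes (median relative to all genes 0.45, 0 called over all genes or over the list alone, adjusted p = 2.5e-09, and adjusted p = 0.255 with an estimated correlation) and genes of glycolysis and hypoxia (0.25, 0 called over all genes or over the list alone, adjusted p = 0.0104, and adjusted p = 0.662 with an estimated correlation) were higher with Ino80 siRNA. Lower were the p53 list (-0.34, 3 lower, with 7 over the list alone, adjusted p = 2.0e-05, and adjusted p = 0.112 with an estimated correlation), the pluripotency list (-0.20, 1 lower, with 5 over the list alone, adjusted p = 0.00123, and adjusted p = 0.601 with an estimated correlation) and the Hox list (-0.32, 0 called and 2 lower over the list alone, adjusted p = 0.0147, and adjusted p = 0.662 with an estimated correlation). The pluripotency call was lost with normexp background correction and without Ino80 replicate 1, the glycolysis call without Ino80 replicate 2 and without Ino80c replicate 1, and the Hox call without Ino80 replicate 2 and without Ino80c replicate 2. With Ino80b siRNA, the cholesterol list (0.43, 0 called over all genes or over the list alone, adjusted p = 5.7e-15, and adjusted p = 0.331 with an estimated correlation), the ribosomal protein list (0.14, 0 called over all genes or over the list alone, adjusted p = 3.5e-06, and adjusted p = 0.845 with an estimated correlation) and the INO80 complex list (0.15, Ino80c itself higher, with 1 over the list alone, adjusted p = 0.00503, and adjusted p = 0.354 with an estimated correlation) were higher than with Ino80c siRNA. So was the primed epiblast list (0.20, 0 called over all genes or over the list alone, adjusted p = 0.0395, and adjusted p = 0.354 with an estimated correlation). Lower were the endoderm list (-0.25, 0 called, with 8 lower and 1 higher over the list alone, adjusted p = 0.0041, and adjusted p = 0.354 with an estimated correlation) and the germline list (-0.31, 0 called and 5 lower over the list alone, adjusted p = 0.00503, and adjusted p = 0.845 with an estimated correlation). Without Ino80b and Ino80c, the complex list had an adjusted p of 0.0331 (13 genes, median 0.15, adjusted p = 0.641 with an estimated correlation). The ribosomal and INO80 complex calls were lost with quantile normalization, the latter also without Ino80c replicate 2, the endoderm call without Ino80b replicate 2 and the germline call without Ino80b replicate 1 and without Ino80c replicate 2. The primed epiblast call held in 13 of 21 alternatives.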

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

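Of the alternatives below, an adjusted p under 0.1 and the INO80 complex list without the targeted genes were chosen only after the results were seen. Where no cause is given, the cause was not tested. With 2 arrays per group, the counts depend on single arrays and on how the spread is estimated. Of 7462 values of genes picked by the naming rule under the alternatives, 5621 kept their side of the threshold, 1507 no longer passed, 329 newly passed and 5 reversed. Of 4006 values of gene lists, 3736 kept their side, 169 no longer passed, 98 newly passed and 3 reversed. Directions were compared only for values called in the main fit or under the alternative. An uncalled value that changed sign therefore counts as kept. Of 309 further counts, which leave out the numbers of genes called in each comparison, 197 stayed within 1.5 times and 112 did not. The pluripotency list passed camera in all 21 alternatives with the preset correlation for Ino80 (adjusted p from 1.4e-16 to 6.7e-08), Ino80b (1.0e-11 to 0.00018) and Ino80c (4.6e-12 to 1.2e-05), as did the endoderm and 2-cell-like lists for these knockdowns. None of these lists passed camera with an estimated correlation in these knockdowns (adjusted p from 0.128 to 0.402, all arrays). A term for slide could not be fitted, since each group lies on 1 slide and NT alone on its own. Signal over background limits dim genes, for which bounds are given.

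With normexp background correction, 3833, 3293, 4216 and 5387 genes were called against NT for Ino80, Ino80b, Ino80c and Ino80e, and 981 in all 4. Counts between knockdowns were 46 (Ino80 and Ino80b), 158 (Ino80c and Ino80e), 752 (Ino80 and Ino80c), 3014 (Ino80 and Ino80e), 13 (Ino80b and Ino80c) and 469 (Ino80b and Ino80e). Shared calls summed over pairs came to 12177, 7 lists passed for Ino80, and Ino80e in its own knockdown passed at -1.22 (adjusted p = 0.017). Between Ino80 and Ino80e, Foxd4 reversed to -0.025 and Adamts6 to -0.070.

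Without the filter on dim probes, the counts were 1285 (Ino80), 252 (Ino80b) and 142 (Ino80c) against NT. In the order of pairs above they were 0, 1, 86, 282, 1 and 46, and the shared calls 370. Ino80b in its own knockdown no longer passed (-2.0, adjusted p = 0.0625). Dhrs9 reversed to -0.31 for Ino80c against NT, -0.99 for Ino80c against Ino80e and 0.11 for Ino80b against Ino80c. With only probes well above background on all 10 arrays, 2275 (Ino80b), 2245 (Ino80c) and 504 (Ino80e) genes were called against NT and 229 in all 4. Between knockdowns there were 81 (Ino80c and Ino80e), 350 (Ino80 and Ino80c), 987 (Ino80 and Ino80e), 12 (Ino80b and Ino80c) and 313 (Ino80b and Ino80e), and 5374 shared calls.

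In the authors' deposited table, 2333 (Ino80b; 886 higher and 1447 lower), 2219 (Ino80c; 619 and 1600) and 1103 (Ino80e; 236 and 867) genes were called against NT and 457 in all 4. Between knockdowns there were 22 (Ino80 and Ino80b), 165 (Ino80c and Ino80e), 851 (Ino80 and Ino80c), 1661 (Ino80 and Ino80e) and 411 (Ino80b and Ino80e), with 6415 shared calls and Ino80e in its own knockdown at -1.41 (adjusted p = 0.0372). With quantile normalization there were 25 (Ino80 and Ino80b), 27 (Ino80c and Ino80e) and 2 (Ino80b and Ino80c), and the ribosomal protein list reversed to -0.042 for Ino80b and -0.054 for Ino80e against NT. With median centring, Ino80c and Ino80e differed in 15 genes.

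With only the arrays of the groups compared, 0 genes passed limma against NT for Ino80, Ino80b and Ino80c, 0 in each of the 6 pairs and 0 were shared. The targets kept their values with an adjusted p of 0.117 for Ino80 (-1.20), 0.142 for Ino80b (-2.0) and 0.146 for Ino80c (-2.34). With only the arrays of the slide, 0 genes passed for Ino80 and Ino80b and 0 for Ino80c and Ino80e. The fit to fewer arrays leaves fewer residual degrees of freedom.

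With replicate number as a block, 4888, 3590, 3712 and 1973 genes were called against NT and 746 in all 4. Between knockdowns there were 72 (Ino80 and Ino80b), 304 (Ino80c and Ino80e), 721 (Ino80 and Ino80c), 1982 (Ino80 and Ino80e) and 841 (Ino80b and Ino80e), with 10584 shared calls and Ino80e in its own knockdown at -1.20 (adjusted p = 0.0422). Deviations of arrays of the same number correlated across genes by 0.00 to 0.32 over the 10 pairs of groups, and nothing in the labels pairs the numbers. With a trend and robust estimation of the prior, 2829 (Ino80b), 2529 (Ino80c) and 1701 (Ino80e) were called against NT and 568 in all 4. Between knockdowns there were 47 (Ino80 and Ino80b), 129 (Ino80c and Ino80e), 454 (Ino80 and Ino80c), 1138 (Ino80 and Ino80e) and 370 (Ino80b and Ino80e), with 7785 shared calls and Ino80e in its own knockdown at -1.20 (adjusted p = 0.0364). With array weights, 678 (Ino80), 529 (Ino80b) and 187 (Ino80c) were called against NT, 243 for Ino80c and Ino80e, 37 for Ino80b and Ino80c and 722 for Ino80b and Ino80e, with 580 shared calls.

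With a 2-fold threshold added, which can only remove calls, 1174 (Ino80), 621 (Ino80b) and 674 (Ino80c) remained against NT, 389 for Ino80 and Ino80e, and 1087 shared calls. At an adjusted p under 0.1 there were 4641, 3425, 3751 and 2118 against NT. With an estimated correlation, 0 lists passed camera for Ino80, 0 for Ino80b, 0 for Ino80c and 0 for Ino80e against NT, while 2, 3, 2 and 0 had an unadjusted p under 0.05. By fry 5, 6, 5 and 0 lists passed, and 7, 7, 8 and 3 had an unadjusted p under 0.05.

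Leaving out each array in turn, the counts against NT ranged from 560 to 3296 (Ino80), 0 to 2856 (Ino80b), 0 to 3142 (Ino80c) and 0 to 587 (Ino80e), and from 0 to 448 in all 4, with a lone array assumed to vary like the other groups. Without NT replicate 1 the counts of Ino80b, Ino80c and Ino80e were 2856, 3142 and 587. Without NT replicate 2, 747 of 832, 27 of 36 and 9 of 11 calls for Ino80, Ino80b and Ino80c had also been called in the same direction with all arrays. Between knockdowns the counts ranged from 0 to 9 (Ino80 and Ino80b), 0 to 17 (Ino80c and Ino80e), 0 to 188 (Ino80 and Ino80c), 42 to 747 (Ino80 and Ino80e), 0 to 8 (Ino80b and Ino80c) and 0 to 137 (Ino80b and Ino80e), and shared calls from 48 to 7533. The target Ino80b ranged from -2.24 to -1.76 and Ino80c from -2.49 to -2.19. Lists that passed numbered 3 to 8 for Ino80 and 1 to 3 for Ino80e. The glycolysis and hypoxia list for Ino80 against Ino80b ranged from -0.092, reversed, without Ino80 replicate 2 to 0.48 without Ino80 replicate 1.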

Other observations

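All tests of explanations in this part were chosen only after the result was seen, as were the genes of this paragraph and the next. Bmp4 fell and Bmp8b, another gene of the family, rose in the Ino80, Ino80b and Ino80c knockdowns. Etv4, an ETS factor gene downstream of FGF signalling, fell with Ino80 siRNA (-0.73 ± 0.14, adjusted p = 0.019) and Ino80b siRNA (-0.65 ± 0.14, adjusted p = 0.0412), and was at -0.56 ± 0.14 (adjusted p = 0.0556) with Ino80c siRNA and -0.17 ± 0.14 (adjusted p = 0.434) with Ino80e siRNA. Etv5, of the same family, fell with Ino80 siRNA (-0.70 ± 0.18, adjusted p = 0.0464). With Ino80b, Ino80c and Ino80e siRNA it was at -0.70, -0.60 and -0.57 (each ± 0.18, adjusted p = 0.0594, 0.0808 and 0.106). Lifr, which encodes a receptor for leukaemia inhibitory factor, fell with Ino80 siRNA (-0.67 ± 0.14, adjusted p = 0.0244). With the Ino80b, Ino80c and Ino80e siRNAs it was at -0.33, -0.054 and 0.20 (adjusted p = 0.163, 0.799 and 0.368), and it was lower with Ino80 than with Ino80e siRNA (-0.87 ± 0.14, adjusted p = 0.0233). Id1, a target of BMP signalling, was not called with Ino80, Ino80b, Ino80c or Ino80e siRNA (-1.53, -0.39, -0.40 and 0.09, each ± 0.42, adjusted p = 0.056, 0.572, 0.521 and 0.904).

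Rhox5 fell with Ino80 siRNA (-2.16 ± 0.21, adjusted p = 0.00314), was not called with Ino80b siRNA (0.25 ± 0.21) or Ino80e siRNA (-0.07 ± 0.21), and rose with Ino80c siRNA (0.95 ± 0.21, adjusted p = 0.0445). It was lower with Ino80 than with Ino80b siRNA, within a slide (-2.42 ± 0.21, adjusted p = 0.0194). Rhox6, of the same cluster, rose with Ino80, Ino80b and Ino80c siRNA (0.95, 0.80 and 1.21, each ± 0.14). With Ino80e siRNA it was at 0.83 ± 0.14 and was not called (adjusted p = 0.0705). Rhox9, of that cluster too, rose with Ino80c siRNA (0.91 ± 0.15, adjusted p = 0.0269) and was not called with Ino80, Ino80b or Ino80e siRNA (0.14, 0.31 and 0.28). The imprinted gene Dlk1 rose with Ino80, Ino80b and Ino80c siRNA (0.76, 0.72 and 1.12, each ± 0.12) and was not called with Ino80e siRNA (0.34 ± 0.12). Peg10 (-1.50 ± 0.30, adjusted p = 0.0755) and Peg3 (-1.45 ± 0.39, adjusted p = 0.0921), which are imprinted too, were not called in the Ino80e knockdown. Nor were they called with Ino80, Ino80b or Ino80c siRNA. There Peg10 was at -0.70, -0.56 and -1.12 (adjusted p = 0.16, 0.257 and 0.0669) and Peg3 at -0.87, -0.52 and -0.35 (adjusted p = 0.173, 0.407 and 0.547).

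Relative to all genes, the pluripotency and endoderm lists were lower in the Ino80, Ino80b and Ino80c knockdowns than in NT, and NT lay alone on its slide. Not set against other genes, the endoderm list in the Ino80c knockdown had a raw median of -0.08 and did not pass fry (adjusted p = 0.269). Over the 30 members called lower in the Ino80 or Ino80b knockdown, the median difference of Ino80c from Ino80e, which share a slide, was -0.65 less that of all genes, with 26 below 0, against -0.13 to 0.02 for the central 95% of 10000 random lists, and their median against NT was -0.88. The within-slide difference goes against the slide as the whole cause for Ino80c, but random lists measure the spread over genes and not between arrays. Between Ino80c and Ino80e, both whole lists passed camera at the preset correlation. Neither passed with an estimated correlation (adjusted p = 0.238 for pluripotency and 0.12 for endoderm), so the slide stays open for Ino80c. Without either NT array, the pluripotency list had a camera adjusted p of 3.2e-08 or less in the Ino80 knockdown (list medians -0.89 and -0.58). This argues against 1 deviating NT array as the whole cause there (with all arrays, adjusted p = 0.128 with an estimated correlation). Over the 12 members called lower in the Ino80c knockdown, the median difference of Ino80 from Ino80b was -0.22 (random lists -0.19 to 0.08), beside -1.89 against NT, but a slide effect and a change shared by both knockdowns would each leave it small. With NT alone on its slide, the slide and the knockdown therefore cannot be told apart for Ino80, and with NT as the only control an effect of the siRNAs other than loss of the subunits stays open.

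Ino80b RNA was lower in the Ino80c and Ino80e knockdowns, which share slide 3. On the mean of that slide its difference from NT was -1.25. Of 2643 probes of like NT signal, 19, or 0.719%, were lower by as much, which argues against a general loss there of signal at that level. The probe (NT mean -1.28) was above background on all 10 arrays, so dim probes were not covered. A defect of this probe on slide 3 and a change of Ino80b RNA with loss of the other subunits both stay open.

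No gene passed in the Ino80e knockdown. The log2 change of Ino80e in its knockdown differed from that of Ino80 in its own by -0.0058 (95% interval -0.72 to 0.71), which leaves open whether the target was lost less. Over the 1029 genes called in the same direction for Ino80 and Ino80b, the Ino80c knockdown lay further in that direction than the Ino80e knockdown by a median of 0.27, with 226 genes the other way, against -0.02 to 0.02 for random lists. The random lists measure the spread over genes and not between arrays. A candidate explanation, which they do not settle, is that many of these genes changed less with Ino80e siRNA. Protein levels were not analysed here, so a lasting Ino80e protein stays untested.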
